A study of Mus musculus with 14 samples.

How the data were processed

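RNA sequencing of mouse dorsal root ganglia was analysed in 14 samples from 2 tables of gene counts. Per the labels, total RNA was extracted with Trizol and an RNeasy kit before library construction; the protocol covers cultured cells and tissues alike, so it is not stated here whether cells were cultured. The deposited values of both tables are counts, whole numbers per gene that were not normalized by the authors. Per the submitters' processing notes the genome build was GRCm39; the aligner, the counter and their settings are not given in the sources used here. The deposited p75 count table lists 20833 gene symbols, and the deposited counts for 5xFAD and wild type cover 56691 Ensembl genes with their symbols. Where several Ensembl genes shared a symbol, the one with the most counts kept it and the others stayed under their identifiers. No coordinates are given, since the reference annotation at hand was of an older build; it was used only for gene lengths and GC content, which were found for 99.3% of the p75 genes tested.

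Groups were taken from the sample titles and genotypes. The p75 table names its knockout columns P75-Adv, where the titles have P75-KO, and the labels do not explain Adv. These columns were matched to knockout samples 1 to 3 by number and by elimination, since no other samples remained. No library was a copy of another: within groups at least 23.6% of genes differed by more than counting noise. Total counts ranged from 4731119 to 6052690 in the p75 table and from 13907070 to 19837836 in the 5xFAD table, and the common dispersion was 0.3 in the former and 0.023 in the latter, so the p75 table gives the less precise fold changes.

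Each comparison was fitted on its own table in R 4.3.3 with edgeR 4.0.16: filterByExpr with the groups, TMM scaling, robust glmQLFit and glmQLFTest, without covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05. This left 11890 genes in the p75 table and 15845 in the 5xFAD table. CPM were computed from the deposited counts with TMM-scaled library sizes. Standard errors (SE) are the size of the log2 fold change divided by the square root of its quasi-likelihood F. Ngfr, App and Thy1 were also tested by exact permutation of the group labels.

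The tests, the lists and the rule for named genes were chosen before the data were examined. Named genes were fixed targets, of which Ngfr and, for the transgenes, App and Thy1 are given (the results of some named genes are not reported here); the 8 largest increases and 8 largest decreases among called genes with groups that did not overlap and a higher mean of at least 1 CPM, leaving out predicted genes; up to 12 further members of the lists by adjusted p, at most 2 per list; and up to 4 members of each list described. Where no gene was called, the 5 smallest p in each direction were named instead. The 44 gene lists covered cell types of the ganglion and its surroundings, families of secreted factors, neuronal functions and cell states, and those with at least 4 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Of the lists, 37 were tested in the p75 table and 38 in the 5xFAD table. Secreted factors called lower were compared with other genes by Fisher's exact test, and, after the data were seen, so were those called higher.

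The same replicate numbers occur in both groups of each table. In the p75 table the deviations from the group means correlated between libraries of equal number by 0.344, 0.310 and 0.581, which passed the rule set for pairing (each over 0.1), so values with the replicate number as a block are given where they change a call. Libraries of replicates 1 and 2 also correlated across numbers, by 0.375 and 0.445, so the pairing comes from the data and mainly parts replicate 3 from the others.

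Alternatives chosen in advance were the scaling factors of DESeq2 1.42.0, upper-quartile scaling, the DESeq2 test, limma-voom, no filter, a mean of at least 5 CPM, the replicate block, a test against a 1.2-fold change and leaving out each library. Added after the data were seen were fits without replicate 3 or with it as a batch term, fits within or adjusted for the split of the 5xFAD table, counts corrected for tag collisions, and DESeq2 with the block. The code was tested on simulated data in which 200 genes with a mean of at least 5 CPM changed, so the shares do not cover scarcer genes. Without the block, 94% of 2-fold and 96% of 4-fold changes were recovered in the 5xFAD table and 0% and 8% in the p75 table. Of the unchanged genes, 10 of 15429 and 4 of 11314 were called. Unlike the real libraries, these simulated ones held no shift shared by libraries of equal number.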

Results

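Gene expression was measured by RNA sequencing of mouse dorsal root ganglia, which hold the cell bodies of sensory neurons among Schwann cells, satellite glia, connective tissue, vessels and immune cells. The 14 libraries formed 4 groups. In 1 table, 3 libraries came from mice with floxed alleles of the p75 neurotrophin receptor and 3 from p75 knockouts. In the other, 4 libraries came from wild-type mice and 4 from 5xFAD mice, a transgenic model of Alzheimer disease that carries mutant human transgenes, among them APP, under a Thy1 cassette. Total counts were 5104385, 5420655 and 6052690 in floxed replicates 1, 2 and 3, and 4800323, 4731119 and 5962350 in knockout replicates 1, 2 and 3. They were 16880129, 13970593, 18059928 and 19837836 in wild-type replicates 1 to 4, and 18494210, 19122761, 13907070 and 17583410 in 5xFAD replicates 1 to 4. Each comparison was tested within its own table. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

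The p75 comparison asked which genes, and among them which secreted factors, had lower expression in the p75 knockout than in the floxed control. The table names its knockout columns P75-Adv, a term that the labels do not explain. Ngfr, the gene that encodes p75, stood at 129, 124 and 91.1 CPM (counts scaled to library size) in floxed replicates 1, 2 and 3, and at 22.2, 24.9 and 37.7 CPM in knockout replicates 1, 2 and 3. The means were 115 ± 20.7 CPM (SD, n = 3) and 28.3 ± 8.28 CPM (SD, n = 3), so that the knockout libraries held 19.3% to 32.8% of the floxed mean. The log2 fold change was -2.02 with a standard error (SE) of 0.35. The exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 can give. The edgeR quasi-likelihood test gave an unadjusted p of 0.000411 and an adjusted p of 0.9999. DESeq2 called Ngfr lower at an adjusted p of 0.0141, and edgeR on replicates 1 and 2 alone, a setting chosen after the data were seen, gave -2.43 with an adjusted p of 0.00541.

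Calca, which encodes the pain neuropeptide CGRP, stood at 134, 183 and 25.4 CPM in the floxed libraries and at 9.88, 16.6 and 3.53 CPM in the knockouts. With the replicate number as a block, Calca was the 1 gene that edgeR called, with a log2 fold change of -3.39 (SE 0.30) and an adjusted p of 0.0116. Without the block its value was -3.52 (SE 0.83) and was not called (adjusted p = 0.9999). Tac1, the precursor of substance P, had a log2 fold change of -3.83 (SE 1.17), and Scg2, a granin of secretory vesicles, -2.08 (SE 0.71). Il1rn, the interleukin 1 receptor antagonist, stood at -3.64 (SE 0.79). Gbp2b, an interferon-induced GTPase, stood at -4.85 (SE 1.19), and Trf, the iron carrier transferrin, at -1.40 (SE 0.31). Tac1, Il1rn and Gbp2b were scarce, with knockout means of 0.416, 0.615 and 0.646 CPM, so their fold changes rest on few counts. Igf1, a growth factor for bone and nerve, had -2.39 (SE 0.66). Spp1, which encodes osteopontin, had -1.33 (SE 0.39), and Dcn, the matrix proteoglycan decorin, had -2.02 (SE 0.64). In each of these genes the 3 knockout libraries lay below the 3 floxed ones (groups of 3 part by chance in 10% of genes), and edgeR without the block gave each an adjusted p of 0.9999. Within replicate 3 the log2 ratios of Scg2, Dcn and Spp1 were small, at -0.01, -0.35 and -0.40. Within replicates 1 and 2 they were -2.72, -3.09 and -1.82. For Tac1 the values were -6.58 and -2.84. Knockout replicate 3 held 0 CPM of Tac1 against 8.925 CPM in floxed replicate 3. The size of the former value is therefore set by the small count added before taking logs.

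**Figure D1:**
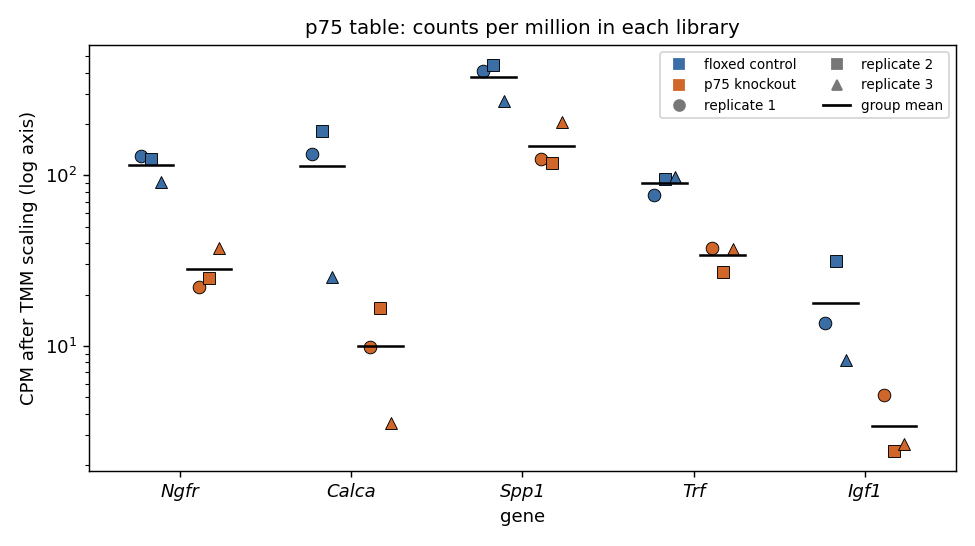
CPM (log axis) of Ngfr, Calca, Spp1, Trf and Igf1 in each of the 3 floxed (blue) and 3 p75 knockout (orange) libraries; the marker shape gives the replicate number and the black bar the group mean. The knockout libraries lie below the floxed libraries in all 5 genes, and in Calca both replicate 3 libraries lie below the others of their group.

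The genes with the smallest p among those higher in the knockout were Cdh13, a cadherin, with a log2 fold change of 3.58 (SE 0.83), and Rnd2 with 1.42 (SE 0.43). They were followed by Lrrc1 with 2.50 (SE 0.78), Tulp2 with 2.16 (SE 0.67) and B4galt2 with 1.39 (SE 0.45). Cdh13, Lrrc1 and Tulp2 were scarce in the floxed libraries, with means of 0.475, 1.51 and 1.88 CPM. Nefh, the heavy neurofilament of large myelinated neurons, stood at 2.35 (SE 0.87), and the guidance ligand Ntn4 at 2.04 (SE 0.84). In both genes the groups overlapped, and 8 of the 13 tested genes of large myelinated neurons lay below 0. Rbfox3, a nuclear marker of neurons, had -3.25 (SE 1.11), with means of 4.16 CPM in floxed and 0.429 CPM in knockout libraries. The pan-neuronal list that holds it had a median of -0.16, with 6 of 13 members above 0. C1qb, a complement gene of macrophages, had -2.11 (SE 0.82). Lilrb4a, an inhibitory receptor of myeloid cells, had -2.26 (SE 0.95), and the Schwann cell claudin Cldn19 -1.80 (SE 0.72). None of these passed the edgeR test. App and Thy1 had log2 fold changes of -0.09 (SE 0.47) and 0.39 (SE 0.67), each within its error.

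Over all 11890 genes tested, edgeR called 0 at an adjusted p under 0.05 and limma-voom called 0. DESeq2 called 4, all lower: Calca, Gbp2b, Ngfr and Ppp1r1c, the last named only because it was called. At an unadjusted p under 0.05, 140 genes stood out in edgeR, 54 higher and 86 lower, where 594.5 would be expected by chance. The number was 330 with the replicate block. In fits chosen after the data were seen, it was 534 with a batch term for replicate 3 and 745 in replicates 1 and 2 alone. The fit without the block thus gave fewer small p than chance, so its 0 calls do not show that no gene changed. Replicates 1 and 2 alone gave 6 calls, all lower: Calca, Ngfr, Gbp2b, Spp1, Dcn and Ifitm1, an interferon-induced membrane protein named because it was called. In data simulated from these libraries, the changed genes had a mean of at least 5 CPM. There edgeR recovered 8% of 4-fold changes and 0% of 2-fold changes without the block. In separate data simulated with a mean for each replicate number, it recovered 68% and 17% with the block. The former data held no shift shared by libraries of equal number. The shares therefore do not give the power of the real fits or the gain from the block. The libraries of replicate 3 stood apart from the other 4 in both groups. The first principal component held 58.9% of the variance and separated them. In all, 3623 genes differed between them and replicates 1 and 2 in edgeR with genotype in the model.

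Among secreted factors, 118 of the 244 genes in the 8 lists of ligands, peptides and cytokines fixed in advance were tested, and edgeR called 0 of them lower and 0 higher (DESeq2 and the replicate block 1 lower each, Calca). Adjusted over the list alone, the counts were 0 without the block, and 3 lower and 1 higher with it. At an unadjusted p under 0.05, 5 secreted factors were lower, Igf1, Spp1, Calca, Scg2 and Tac1, and 1, Ntn4, was higher. The lower ones made up 4.24% of the secreted factors tested against 0.688% of the other genes (Fisher's exact test, two-sided p = 0.00162). For the higher one the shares were 0.847% and 0.45% (p = 0.417 by the same exact test, chosen for this direction after the data were seen). With the block 11 were lower and 6 higher at that threshold, and both shares exceeded those of the other genes. They were 9.32% against 1.43% lower (Fisher's exact test, p = 1.57e-06) and 5.08% against 1.23% higher (p = 0.0039).

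By gene list, 9 of the 37 lists tested passed in camera, 8 toward lower and 1 toward higher expression in the knockout, while no single member passed the edgeR test. With an estimated correlation between genes 0 lists passed, and so did 0 in fry, whose smallest adjusted p was 0.554. Macrophage markers had a median log2 fold change of -1.84, with 5 of 6 members below 0 (camera adjusted p = 2.6e-05; adjusted p = 0.259 with an estimated correlation). In this list Tyrobp had -2.56 (SE 1.16) and C1qb -2.11 (SE 0.82). The median over replicate 3 against replicates 1 and 2 was 1.65 for the same macrophage list, so these markers also moved with the libraries that stood apart. Peptidergic nociceptors, the pain neurons that make CGRP and substance P, had a median of -2.42, with 3 of 5 members below 0, among them Calca, Tac1 and Gal (camera adjusted p = 0.00021; adjusted p = 0.259 with an estimated correlation). Of the 5, 2 were lower when adjusted over the list alone. The list of neuropeptides and hormones shares Calca, Tac1, Gal and Adcyap1 with it. It had a median of -0.38 over 17 members (adjusted p = 0.00209; adjusted p = 0.259 with an estimated correlation), and 1, again Calca, was lower when adjusted over the list alone.

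The plaque-associated microglia genes had a median of -0.30, with 12 of 15 members below 0 (adjusted p = 0.000972; adjusted p = 0.259 with an estimated correlation). Fibroblast and extracellular matrix genes, such as Dcn and Bgn, had a median of -0.44, with 14 of 16 below 0 (adjusted p = 0.00209; adjusted p = 0.775 with an estimated correlation). Interferon response genes, such as Bst2 at -1.02 (SE 0.43), had a median of -0.50, with 17 of 19 below 0 (adjusted p = 0.0066; adjusted p = 0.781 with an estimated correlation), and differed between replicate 3 and the others by a median of -2.97. Secreted factors with roles in bone had a median of -0.09, with 20 of 37 below 0 (adjusted p = 0.00507; adjusted p = 0.73 with an estimated correlation). Cytokines and chemokines had a median of -0.22, with 14 of 20 below 0 (adjusted p = 0.00667; adjusted p = 0.259 with an estimated correlation). Cell cycle genes, such as Bub1b at 0.94 (SE 0.60), had a median of 0.52, with 20 of 25 above 0 (adjusted p = 0.033; adjusted p = 0.775 with an estimated correlation). Between replicate 3 and replicates 1 and 2 the median differed by -1.50 for fibroblasts, -1.02 for bone factors, -0.98 for peptidergic nociceptors and -0.86 for the cell cycle. It differed by -0.53 for neuropeptides, -0.33 for cytokines and 0.33 for plaque-associated microglia. With the replicate block 18 lists passed in camera, 4 higher and 14 lower, and again 0 with an estimated correlation, where the smallest adjusted p was 0.421. The lists that passed only with the block were cytosolic ribosomal proteins (adjusted p = 3.06e-05), satellite glia (0.0418) and Wnt factors (0.0283) toward higher expression, and mural cells (0.00886), antigen presentation (0.00993), Schwann cell myelin (0.0159), endothelium (0.0228), complement (0.023) and pan-neuronal genes (0.0493) toward lower. Between replicate 3 and replicates 1 and 2 these lists differed by 1.31 for ribosomal proteins, -2.10 for satellite glia, -1.95 for Wnt factors and -1.44 for myelin. The other medians were -0.93 for complement, 0.55 for endothelium, -0.49 for antigen presentation, -0.17 for mural cells and -0.04 for pan-neuronal genes.

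Leaving out 1 library ended the call of 6 of the 9 p75 lists. The largest adjusted p was 0.695 for fibroblasts, 0.133 for cytokines and 0.481 for bone factors without floxed replicate 2, 0.126 for neuropeptides and 0.902 for the cell cycle without knockout replicate 1, and 0.893 for interferon genes without knockout replicate 3. Fibroblasts, bone factors and interferon genes also lost it without floxed replicates 1 and 2 or knockout replicate 3, neuropeptides without floxed replicates 1 and 2, and the cell cycle without those and knockout replicate 2. The lists of macrophages, peptidergic nociceptors and plaque-associated microglia stayed past the threshold in all 6 such fits. Median, mean and test differed in sign for Wnt factors, FGF ligands, axon guidance ligands, large myelinated neurons, unfolded protein response, growth factors and nerve injury, none of which passed without the block.

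The other table compared the ganglia of 5xFAD and wild-type mice. In 5xFAD, genes of neuronal identity and of the response to nerve injury were higher as lists, also with an estimated correlation in the fit without covariates, and Ngfr was lower. Lists of channels and of neuropeptides passed toward higher expression with the preset correlation but not with an estimated one (adjusted p = 0.201 and 0.13). Ngfr fell from 667 ± 34.7 CPM (SD, n = 4) to 410 ± 38.5 CPM (SD, n = 4), which is 61.6% of the wild-type mean, with a log2 fold change of -0.70 (SE 0.08) and an adjusted p of 0.00128 in edgeR. It was -0.66 within replicates 1 and 2 and -0.76 within replicates 3 and 4. Its exact two-sided permutation p was 0.0286, the smallest that 4 libraries against 4 can give. Reads of the human APP transgene or of its Thy1 cassette could align to the mouse genes App and Thy1. App had a log2 fold change of 0.14 (SE 0.08; adjusted p = 0.411) and Thy1 0.87 (SE 0.32; adjusted p = 0.242). Neither passed the edgeR test. Thy1 passed within replicates 1 and 2 alone, at 0.51. Thy1 is itself in the list of large myelinated neurons. Pan-neuronal genes had a median of 1.34 over all libraries and 0.95 within replicates 1 and 2. The values of Thy1 therefore cannot tell transgene reads from the rise of neuronal genes.

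The edgeR test called 570 of 15845 genes, 406 higher and 164 lower in 5xFAD. Of these, 257 changed by more than 2-fold, 224 higher and 33 lower. The libraries also split by replicate number, with replicates 1 and 2 apart from 3 and 4 in both genotypes. With this split as a term 1866 genes were called, within replicates 1 and 2 alone 2053, and within replicates 3 and 4 alone 771. The balance of directions varied too: 71.2% of the 570 calls were higher in 5xFAD, against 63.5%, 49.7% and 73.2% in these 3 fits. With the split as a term, chosen after the data were seen, the lists that passed with an estimated correlation were nerve injury and channels (adjusted p = 0.0354 each) and Schwann cell myelin (0.0428). The pan-neuronal list did not (0.0827). Leaving out wild-type replicate 1 lowered the count to 237, 5xFAD replicate 4 to 283, 5xFAD replicate 1 to 323 and 5xFAD replicate 2 to 376.

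Pan-neuronal genes rose together: 11 of 13 were called higher and 0 lower, and 13 of 13 were higher when adjusted over the list alone. The median log2 fold change was 1.34, with 0.95 within replicates 1 and 2 and 1.55 within replicates 3 and 4 (camera adjusted p = 9.94e-38; adjusted p = 0.0296 with an estimated correlation). With an estimated correlation camera did not pass the list within replicates 1 and 2 (adjusted p = 0.382) or within replicates 3 and 4 (adjusted p = 0.131). Syt1, the calcium sensor of transmitter release, rose by 1.36 (SE 0.13) from 6.49 to 16.7 CPM, and the neuronal tubulin gene Tubb3 by 0.65 (SE 0.07). The vesicular glutamate transporter gene Slc17a6 rose by 1.64 (SE 0.17) and Stmn2, a tubulin-binding protein of growing axons, by 1.34 (SE 0.14). Uchl1 and Isl1 did not pass, at 0.35 (SE 0.14) and 0.94 (SE 0.31). Levels in the wild-type libraries were uneven: Rbfox3 stood at 0.558 to 2.53 CPM and Isl1 at 1.12 to 2.88 CPM, against 225 to 268 CPM for Tubb3. Except for Tubb3 and Pou4f1, wild-type replicate 2 was the highest wild-type library in the genes of this list. Prph, for example, stood at 90.2 CPM there and at 49.1 to 65.5 CPM in the other wild-type libraries. Mapt, which encodes the axonal protein tau, rose by 1.19 (SE 0.13).

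**Figure D2:**
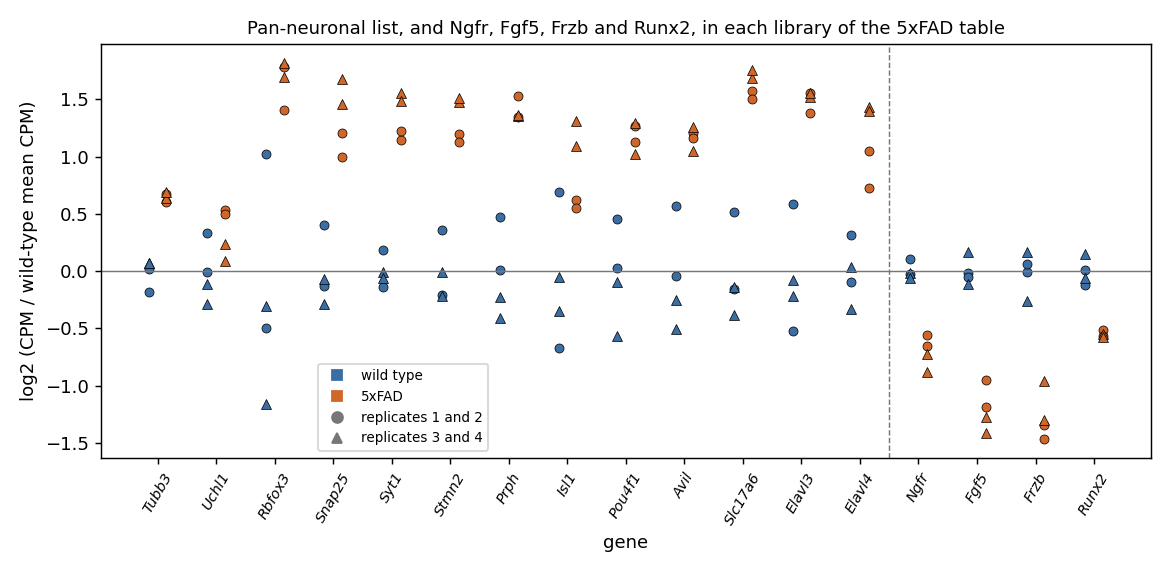
Log2 ratio of CPM to the wild-type mean (vertical axis) for the 13 tested genes of the pan-neuronal list, left of the dashed line, and for Ngfr, Fgf5, Frzb and Runx2, right of it, in each of the 4 wild-type (blue) and 4 5xFAD (orange) libraries; circles are replicates 1 and 2, triangles replicates 3 and 4. Apart from Isl1, where 1 wild-type library lies within the 5xFAD range, and Uchl1, the 5xFAD libraries lie above every wild-type library in the neuronal genes and below every one in the 4 others.

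Of 28 voltage-gated and sensory channels 9 rose and 1 fell, with a median of 0.84 (camera adjusted p = 3.14e-12; adjusted p = 0.201 with an estimated correlation). Adjusted over the list alone, 10 rose and 1 fell. Scn10a, the sodium channel Nav1.8 of nociceptors, rose by 1.36 (SE 0.10; adjusted p = 0.000358) and the N-type calcium channel gene Cacna1b by 1.29 (SE 0.17). Of 9 peptidergic nociceptor genes 3 rose (6 higher and 2 lower when adjusted over the list alone): Trpv1, the heat and capsaicin receptor, by 1.75 (SE 0.32), Calca by 1.52 (SE 0.28) and the neuropeptide gene Gal by 2.29 (SE 0.50). This list passed in camera (adjusted p = 0.00136) but not with an estimated correlation (adjusted p = 0.427) nor within replicates 1 and 2 (adjusted p = 0.222). Gal was not called in 6 of the 8 fits that left out 1 library, with adjusted p from 0.0194 to 0.103. Of 9 genes of non-peptidergic and itch neurons 1, the ATP receptor gene P2rx3, rose, by 1.28 (SE 0.24) (camera adjusted p = 0.00864; adjusted p = 0.201 with an estimated correlation). In this list 4 were higher when adjusted over the list alone. Of 14 genes of large myelinated neurons 3 rose, Nefl by 1.33 (SE 0.20), Nefh by 1.48 (SE 0.26) and Cntnap2 by 1.36 (SE 0.23) (camera adjusted p = 0.000625; adjusted p = 0.478 with an estimated correlation). Of them 5 were higher when adjusted over the list alone. Within replicates 1 and 2 this list pointed the other way in camera (adjusted p = 0.865) although its median was 0.45. Of 5 genes of low-threshold C fibres and cold neurons 2 fell, Slc17a8, the vesicular glutamate transporter of C-fibre touch neurons, by 1.64 (SE 0.21) and Zfp521 by 0.52 (SE 0.11) (camera adjusted p = 0.0399; adjusted p = 0.427 with an estimated correlation; adjusted p = 0.558 within replicates 3 and 4). Adjusted over the list alone, 2 fell and 1 rose.

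Of 18 genes of nerve injury and regeneration 7 rose and 0 fell, with a median of 0.64 (camera adjusted p = 1.88e-11; adjusted p = 0.0296 with an estimated correlation). With an estimated correlation camera did not pass this list within replicates 1 and 2 (adjusted p = 0.354) or within replicates 3 and 4 (adjusted p = 0.131). Adjusted over the list alone, 10 rose and 1 fell. Sprr1a, which is induced in injured sensory neurons, rose by 2.06 (SE 0.25) from 6.76 to 28.2 CPM, the growth cone protein gene Gap43 by 1.42 (SE 0.19) and Gpr151 by 1.75 (SE 0.24). Of 22 neuropeptides and secretory granule proteins 8 rose and 1 fell (9 and 2 when adjusted over the list alone), with a median of 0.97 (camera adjusted p = 2.67e-08; adjusted p = 0.13 with an estimated correlation). Scg3 rose by 1.06 (SE 0.09; adjusted p = 0.000453), Chga by 1.50 (SE 0.19) and Chgb by 1.49 (SE 0.24). Ret, the receptor of glial cell line-derived factors, rose by 1.26 (SE 0.12; adjusted p = 0.000736), the largest adjusted p over the 8 fits that left out 1 library being 0.00498.

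Of the genes in the lists of secreted factors 166 were tested, of which 14 rose and 9 fell. The lists followed gene families, so a member such as Fgf12, which rose, or Efnb2, which fell, may not be secreted. Adjusted over the list alone, 19 rose and 14 fell. Larger shares of the secreted factors than of the other genes were called in both directions, 5.42% against 0.989% lower (Fisher's exact test, two-sided p = 5.79e-05) and 8.43% against 2.5% higher (p = 9.67e-05). Of the 14 that rose, 8 were the neuropeptides and granule proteins counted above, which rose beside the pan-neuronal genes. At an unadjusted p under 0.05 the shares were 14.5% against 6.85% lower (p = 0.000559) and 18.7% against 9.19% higher (p = 0.000211, both by Fisher's exact test). Fgf5, a fibroblast growth factor, fell by 1.19 (SE 0.10; adjusted p = 0.000453) from 95.6 ± 8.20 to 41.8 ± 5.74 CPM (SD, n = 4 each, edgeR). The secreted Wnt antagonist Frzb fell by 1.26 (SE 0.12; adjusted p = 0.000857), with -1.44 within replicates 1 and 2 and -1.10 within replicates 3 and 4. The axon repellent Sema3a fell from 11.7 to 5.85 CPM (SE 0.16 on the log2 scale), Bmp4 by 0.80 (SE 0.18) and Ccn2 by 0.50 (SE 0.09), while Ccn3 rose by 0.91 (SE 0.09) and the neuregulin gene Nrg1 by 0.78 (SE 0.16). Runx2, the transcription factor of osteoblast differentiation, fell by 0.55 (SE 0.07; adjusted p = 0.00186). Secreted factors with roles in bone did not pass as a list (camera adjusted p = 0.0735; adjusted p = 0.604 with an estimated correlation). Within replicates 1 and 2 it passed toward lower expression with the preset correlation (median -0.19; adjusted p = 9.62e-08) but not with an estimated one (adjusted p = 0.354), and within replicates 3 and 4 the test pointed the other way (median -0.02; adjusted p = 0.794). Of its 45 members 1 rose and 4 fell, and adjusted over the list alone 2 rose and 6 fell.

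Lists of other cells and cell states passed in camera, but none of those in this paragraph did with an estimated correlation, apart from Schwann cell myelin with the split as a term. Schwann cell myelin genes had a median of 0.40, with 16 of 18 above 0 and none called (camera adjusted p = 0.000231; adjusted p = 0.478 with an estimated correlation). Mag had 1.66 (SE 0.41). Endothelial genes had a median of -0.41, with 11 of 11 below 0 and none called (adjusted p = 5.9e-05; adjusted p = 0.483 with an estimated correlation). Cdh5 had -0.39 (SE 0.13). Macrophage markers had a median of -0.58, with 11 of 11 below 0 and none called (adjusted p = 0.00864; adjusted p = 0.639 with an estimated correlation). That median was -1.44 within replicates 1 and 2 and -0.17 within replicates 3 and 4, where the list did not pass (adjusted p = 0.238). Plaque-associated microglia genes had a median of -0.43 (adjusted p = 0.0207; adjusted p = 0.483 with an estimated correlation), and 1 of 18, B2m, rose, by 0.54 (SE 0.12). That median was -0.92 within replicates 1 and 2 and -0.05 within replicates 3 and 4, where the test pointed the other way (adjusted p = 0.881), and the split as a term ended the call (0.127). Interferon response genes had a median of 0.98, with 22 of 22 above 0 and none called (adjusted p = 8.97e-08; adjusted p = 0.483 with an estimated correlation). Ifit1 had 2.51 (SE 0.77). Of 15 antigen presentation genes 3 rose, H2-K1 by 0.45 (SE 0.08), H2-D1 by 0.45 (SE 0.09) and B2m (adjusted p = 3.55e-05; adjusted p = 0.427 with an estimated correlation). Of them 8 were higher when adjusted over the list alone. H2-K1 and H2-D1 are near-identical, so their reads could have been shared. Cytosolic ribosomal protein genes had a median of -0.14, with 63 of 66 below 0 and none called (adjusted p = 5.81e-05; adjusted p = 0.641 with an estimated correlation). Unfolded protein response genes had -0.12 (adjusted p = 0.0353; adjusted p = 0.287 with an estimated correlation) and cytokines and chemokines -0.21 (adjusted p = 0.0426; adjusted p = 0.576 with an estimated correlation), where 1 of 33, Clcf1, fell. The cytokine median was -0.45 within replicates 1 and 2 and -0.01 within replicates 3 and 4 (adjusted p = 0.712), and the split as a term ended the call (0.0814). The unfolded protein response did not pass within replicates 3 and 4 (adjusted p = 0.0972). In all, 17 of 38 lists passed in camera, 10 higher and 7 lower, 2 of them with an estimated correlation and 7 in fry. Those of macrophages, low-threshold C fibres, cytokines, unfolded protein response and plaque-associated microglia lost their call when 1 library was left out, with adjusted p up to 0.174 (without 5xFAD replicate 2), 0.157 (wild-type replicate 3), 0.249 (5xFAD replicate 1), 0.0825 (wild-type replicate 2) and 0.106 (5xFAD replicate 1). Median, mean and test differed in sign for Wnt factors, nuclear oxidative phosphorylation genes, complement and bone cells, none of which passed.

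**Figure D3:**
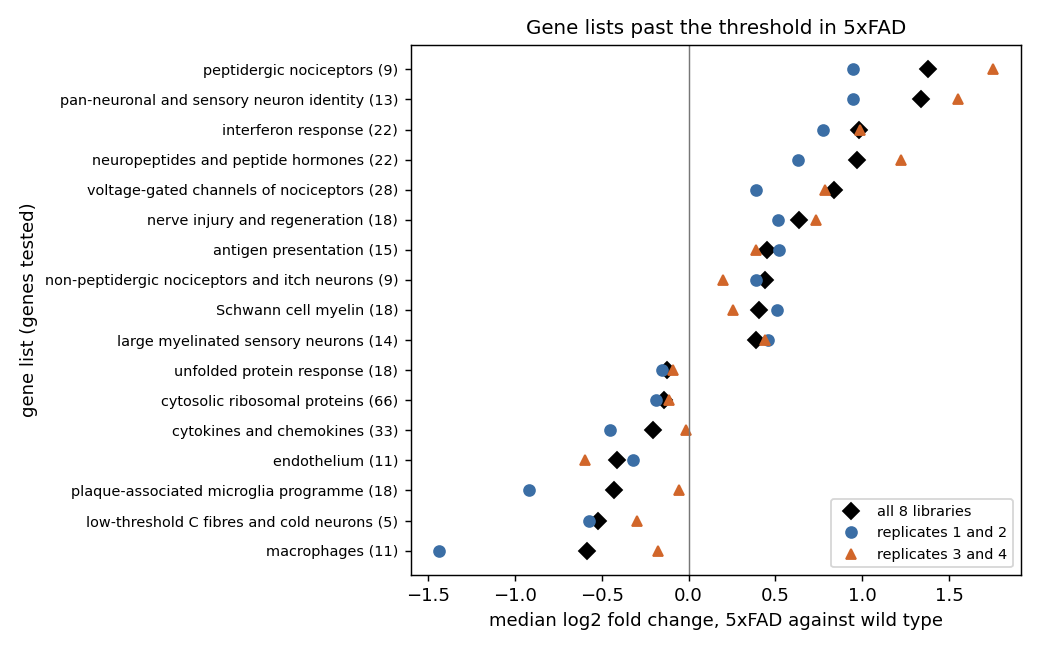
Median log2 fold change, 5xFAD against wild type, of the tested genes of each of the 17 lists that passed in camera, over all 8 libraries (black diamonds), within replicates 1 and 2 (blue circles) and within replicates 3 and 4 (orange triangles); the number of genes tested stands beside each list. The pan-neuronal medians are 1.34, 0.95 and 1.55, and the macrophage medians -0.58, -1.44 and -0.17.

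The largest increases among called genes whose groups did not overlap were those of Kcnc4, a potassium channel gene, at 2.61 (SE 0.53), Galnt14 at 2.44 (SE 0.58), Gal, and Cyp4x1 at 2.13 (SE 0.28). They were followed by Sprr1a, Cdr1os (0.602 against 2.51 CPM, SE 0.48 on the log2 scale), Mir124a-1hg, a host transcript of the neuronal microRNA miR-124, at 1.95 (SE 0.28), and Pip5kl1 at 1.95 (SE 0.32). Most of these were scarce, with Kcnc4 at 1.22 and Pip5kl1 at 1.03 CPM in 5xFAD. The largest decreases were those of Erdr1 at -2.22 (SE 0.31), Tnfsf18 at -1.85 (SE 0.32), Clic6 at -1.84 (SE 0.25) and Ptgs1, which encodes cyclooxygenase 1, at -1.84 (SE 0.28). Next came the myeloid lectin gene Clec4n at -1.77 (SE 0.34), Slc17a8 at -1.64, the leukocyte integrin gene Itgb7 at -1.64 (SE 0.32), and Cdkn1c, a cell cycle inhibitor, at -1.61 (SE 0.18). Erdr1 and Cdr1os are uncertain, the first because of near-identical copies and the second because of its antisense partner. Sizes varied between replicates 1 and 2 and replicates 3 and 4. They were -2.56 and -1.04 for Ptgs1, -2.61 and -1.24 for Clec4n, -2.20 and -0.91 for Itgb7, and 1.68 and 3.33 for Kcnc4. Cyp4x1, at 2.01 and 2.25, and Slc17a8, at -1.72 and -1.57, varied less. Of the 29 named genes called, 23 stayed past the threshold in each fit that left out 1 library. Kcnc4, Galnt14, Gal, Cdr1os, Clec4n and Itgb7 did not, with adjusted p up to 0.0796 (without 5xFAD replicate 4), 0.142 (5xFAD replicate 4), 0.103 (wild-type replicate 1), 0.147 (5xFAD replicate 4), 0.0678 (wild-type replicate 2) and 0.0757 (5xFAD replicate 1).

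Both tables were set side by side over the 11552 genes tested in each. They share no library. Ngfr lay below its controls in both, and with all libraries fitted it passed the edgeR threshold in 5xFAD alone. Calca was called lower in the p75 knockout with the replicate block. In 5xFAD it was called higher in edgeR without the block (adjusted p = 0.0175) but not with it (adjusted p = 0.0783). With edgeR and no block the shared calls were 0. By DESeq2 in both tables there were 3, counted whatever their direction. Of the genes that DESeq2 called lower in the p75 knockout, edgeR called Ngfr lower in 5xFAD and Calca and Ppp1r1c higher. At an unadjusted p under 0.05 in the p75 table, 3 genes were lower in both (Ngfr, Pear1 and Icam1, named because they were counted; 0.875 expected; Fisher's exact test, p = 0.0572), and 8 were lower there and higher in 5xFAD, among them Calca, Scg2 and Rbfox3 (2.08 expected; Fisher's exact test, p = 0.00108). Of the genes higher in the p75 knockout, 2, Nefh and Ptpn22, were higher in both (1.34 expected; p = 0.39) and 2, Prkg2 and Cdh13, lower in 5xFAD (0.565 expected; p = 0.109, both by Fisher's exact test). With the block in the p75 fit, 8 were lower in both (1.86 expected; p = 0.000552), and 14 were lower there and higher in 5xFAD (4.42 expected; p = 0.000139, each by Fisher's exact test). The overlaps of genes higher in the knockout did not pass in Fisher's exact test. With the block 5 were higher in both, the same 2 with Nol3, Coro2a and Nlgn3 (3.66 expected; exact p = 0.419). Another 4 were lower in 5xFAD, the same 2 with Fgf5 and Pdzrn3 (1.54 expected; exact p = 0.0686). Those outside the rule were named because they were counted. The rank correlation across genes of both comparisons, in which genes are not independent replicates, was 0.0492 (Spearman), and leaving out 1 p75 library moved it between -0.0788 (without floxed replicate 3) and 0.155 (without knockout replicate 3).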

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

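The tests of a neuron share, of the split into replicates 1 and 2 against 3 and 4, of the cell makeup and depth of replicate 3, and of a count limit were chosen only after the results were seen. Of 76 groups of 4 libraries tested for a single distant library 2 stood out, where chance gives 3.8. Pip5kl1 was at 0.203 CPM in wild-type replicate 4, against 0.281 to 0.294 CPM in the other wild-type libraries. Ret was at 33.6 CPM in wild-type replicate 2, against 23.17 to 24.95 CPM in the others.

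Neuronal genes were higher in 5xFAD, with a pan-neuronal median of 1.34. Total counts overlapped between the groups, at 13970593 to 19837836 in wild type and 13907070 to 19122761 in 5xFAD. With all libraries thinned to the smallest total the median was 1.31. Thinning keeps the expected fold change, so this test cannot decide on library depth. Each part of the split held as many libraries of either genotype, so the split alone could not raise genes in 5xFAD and its test decides nothing. The lower of the medians within its parts was 0.946, so the rise occurred in both. A higher share of neurons in the 5xFAD samples stays open. Of 37 members of the 4 neuron subtype lists, pan-neuronal genes left out, 5 or 13.5% lay below 0 by more than 2 SE and 18 above 0 by as much. Lists already seen to move cannot decide this. The subtypes moved unequally, with medians of 1.38 for peptidergic, 0.44 for non-peptidergic and 0.39 for large myelinated neurons and -0.52 for low-threshold C fibres. The 5 below were Slc17a8, Spp1, Bmpr1b, Zfp521 and Kit, of which Spp1, Bmpr1b and Kit were named after their values were seen. A change of expression within neurons is the biological alternative and was not tested, so it stays open.

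Replicate 3 of the p75 table differed from replicates 1 and 2 in 3623 genes, 1141 of them by more than 4-fold. Gene length and GC content explained 5.20% of the variance of that difference, which leaves most of it to something else. Depth cannot be the whole cause, because replicate 3 had more counts yet at most 0.952 times as many genes detected as the lowest of the others. A different cell makeup could not be decided: the log2 differences of 66 ribosomal protein genes, 64 of them higher in replicate 3, had an SD of 0.625, against at most 0.351 between libraries of replicates 1 and 2. The design names no biological difference between replicates, and none other than cell makeup was tested.

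In 4 libraries of the p75 comparison, 16 counts lay within 90% or more of 65536, the number of different 8-base tags, and none exceeded it. Gm42418, a locus that collects ribosomal RNA reads, had 65311, 65419, 65469 and 65377 counts in the libraries of replicates 1 and 2. Its variance over mean was 0.0685, where independent counts would give 1. That of the other 3 genes near the limit was 4.39 (Mbp), 13.4 (Malat1) and 42.2 (Cryab). Counts short of a limit can still vary, so these 3 values do not speak against one. These 4 genes were chosen for their counts, so whether a limit on distinct tags per gene applied stays open. Correcting the counts for such a limit left the number of genes called at 0.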

How the results depend on the processing

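The fits without or adjusted for replicate 3, within or adjusted for the 5xFAD split, with counts corrected for tag collisions and with DESeq2 and the block were chosen only after the results were seen. In the p75 table the 0 calls became 4 by DESeq2 (408 genes at an unadjusted p under 0.05), 1 with the replicate block, 1 with a batch term for replicate 3, 1 with the block and corrected counts, 6 in replicates 1 and 2 alone and 15 by DESeq2 with the block (1 higher, 14 lower); each library left out gave 0. Ngfr in the p75 knockout stayed between -2.28 and -1.88 when 1 library was left out; its adjusted p was 0.0141 by DESeq2 (-2.02), 0.00541 in replicates 1 and 2 (-2.43) and 4.07e-06 by DESeq2 with the block (-2.04). Secreted factors called lower were 1 by DESeq2, with the block, with the batch term, and with the block and corrected counts, 2 in replicates 1 and 2, 3 by DESeq2 with the block, and 5 at an unadjusted p under 0.05. Gene lists past the threshold were 18 with the block, 23 in replicates 1 and 2, 17 with the batch term, 17 with the block and corrected counts, 0 with an estimated correlation, 0 in fry, and 4 (without floxed replicate 2) to 24 (without floxed replicate 3) when 1 library was left out. The interferon list ranged from 7.41e-11 to 0.893 in adjusted p over these fits, the last in the other direction. Small and uncalled values changed sign when 1 library was left out: App from -0.40 to 0.16 and Thy1 from -0.28 to 0.91.

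In the 5xFAD table the 570 calls became 991 by DESeq2, 1622 with the replicate block, 252 in a test against a 1.2-fold change, 1866 with the split as a term, 2053 within replicates 1 and 2 and 771 within replicates 3 and 4, and 237 to 516 when 1 library was left out. Of the 570, 569 were shared with DESeq2, 552 with the block, 542 with limma-voom and 234 with the fit without wild-type replicate 1, and none changed sign in any of these. The numbers correlated by 0.118, 0.288, 0.389 and 0.0676, not all over 0.1, so a number was not taken to pair 2 libraries; not every library correlated best with its own number, although replicates 1 and 2 stood apart from 3 and 4. With the block 17 lists passed, 12 higher and 5 lower, and 0 with an estimated correlation (smallest adjusted p = 0.174), and Calca was not called (adjusted p = 0.0783). Thy1 was 0.51 within replicates 1 and 2, now past the threshold. Lists past the threshold were 2 with an estimated correlation, 3 with it and the split as a term, 7 in fry, 18 with the split as a term, 22 within replicates 1 and 2, 15 within replicates 3 and 4 and 13 to 22 with 1 library left out; large myelinated neurons within replicates 1 and 2 (adjusted p = 0.865) and plaque-associated microglia within replicates 3 and 4 (0.881) pointed the other way. Shared calls of both tables, counted whatever their direction, were 3 by DESeq2 and 0 in the other edgeR and limma-voom fits compared. With the block in the p75 table alone there was 1, Calca, in opposite directions. Scaling moved no count past 1.5 times. The causes were not tested; fits without a library have fewer samples. The block changed no other call among the p75 genes named.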

Other observations

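The fits with the split of the 5xFAD table as a term, to real and other splits, were chosen only after the result was seen. The circadian clock list did not pass in 5xFAD (camera adjusted p = 0.205), but 2 of its 17 members fell: Arntl, which encodes BMAL1, by 1.12 (SE 0.19; adjusted p = 0.0125 in edgeR) and its partner Clock by 0.82 (SE 0.14; adjusted p = 0.0135). In the satellite glia list the gap junction gene Gja1 fell by 0.59 (SE 0.11; adjusted p = 0.0155). Fgf12 and Fgf3 rose by 1.18 (SE 0.18) and 1.77 (SE 0.40).

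Other splits of the libraries were fitted in the same way. In the p75 comparison, 3 libraries against 3 make 10 splits, too few for a share under 0.05: the real split called 0 genes and the highest of the others 0, so 10 of 10 were as large. With the replicate block the real split called 1 gene and the highest of the other 3 that part every pair 0, which makes 1 of 4. For gene lists the real split gave 9 and the highest other 17, with 5 of 10 as large.

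For 5xFAD against wild type 2 of 35 splits called as many genes as the real 570, so chance is not excluded by this count. The other was replicates 1 and 2 against 3 and 4, with 1338 genes, which points to a structure of the samples that follows replicate number; the remaining splits called 0. With that split as a term 1866 genes were called between genotypes, and at most 3 in the other splits that take as many libraries from either side. Thus 1 of these 18 splits, the real one, called as many, and 18 are too few for a share under 0.05. For gene lists 6 of 35 splits gave as many as the real 17, the highest other giving 20, so chance is not excluded for the number of lists.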
